A study of Mus musculus with 12 samples.

How the data were processed

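RNA was measured in 12 mouse fetal liver libraries, 3 for each of 4 groups: PIR+ wild type, PIR- wild type, PIR+ KO and PIR- KO. Per the labels, lineage-negative c-Kit+ cells were sorted by flow cytometry into tubes of 100 cells, a fixed amount of ERCC spike-in RNA was added to each tube, and reverse transcription used an oligo-dT primer with a molecular barcode, followed by template switching and PCR. The labels call 6 libraries KO and name no target gene, so no check of the targeted gene was made. They do not say whether the libraries of a group are separate animals, so every p-value measures the spread between these samples.

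Groups were taken from the sample titles, which match the genotype field in all 12 libraries. The markers field gives the opposite PIR sign to the title in 6 of the 12. The source name gives embryonic day 12.5 or 14.5, while the series title gives day 12.5 alone. In all 12 libraries that day goes with the markers field, 12.5 with PIR+ and 14.5 with PIR-, so it is no separate record of stage. The markers field and the series title differ on whether PIR- cells carry IL7R. The levels of the receptor genes in each library, given with the results, were used to check the titles.

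The deposited table holds 23420 genes and 12 value columns in a unit called signal here: molecule counts that the authors divided by a scaling factor per library and rounded to 1 decimal. TopHat2, the mouse genome build mm10 and DESeq2 are named in the deposited processing fields, and their versions, the counting tool and the filters are not given in the sources used here. Whole counts are not claimed, because between 93.0% and 94.2% of the values under 15 in a library lie within rounding (0.055) of a multiple of 1 step, and the rest do not. The step, taken as the value of 1 molecule, was 0.490 to 0.776, and the values correspond to an estimated 208518 to 442714 molecules per library. The deposited sums ran from 155374 to 284648 per library, so the values are not scaled to a common total. Of the 23420 genes, 14177 were above 0 in at least 1 library, and no spike-in rows are in the table. The authors also deposited 2 columns of p-values (unit p_value) from their own DESeq2 tests, for PIR+ against PIR- in wild type and for KO against wild type in PIR+, and their header does not say whether these are adjusted. They are given only beside the fits reported here.

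The main test was limma (version 3.58.1, R 4.3.3) with a trended prior on log2(value + 1), 4 group means and genes with a value of at least 10 in at least 3 libraries, which left 4542 genes. Of these, 4323 have a symbol in GENCODE M21, from which locations on GRCm38 were taken. Benjamini-Hochberg adjusted p-values under 0.05 were called within each comparison. Fold changes are log2 with the standard error of the fit, and the added 1 makes those of genes with low values smaller than the ratio of means. A gene at 0 in all libraries of a group is described as listed at 0, with no fold. The comparisons were PIR+ against PIR- in each genotype, KO against wild type in each subset, the difference between these effects (the interaction) and the averages over subset and over genotype. Library sums were compared by exact two-sided permutation tests. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

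Because the deposited scale keeps differences between library sums, every comparison was repeated after median-of-ratios scaling, which centres the median gene. Calls are said to hold on both scales where they pass in each with the same sign. Of 23 gene lists fixed before the data were examined, 9 had at least 5 tested genes: sort markers, B lineage, lymphoid progenitors, neutrophils and monocytes, erythroid cells, hematopoietic stem cells and multipotent progenitors, cell cycle, the fetal Lin28b program, and cytokine and chemokine receptors. The other 14 had too few and were not tested. The 9 lists were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, and with fry, and list p-values are adjusted over the 9 lists. The lists share genes with each other, Flt3, Ccr9 and Il7r among them.

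Genes were named by a rule set at the same time: up to 8 per direction with the largest fold change among called genes with a mean of at least 20 in the higher group and no overlap between the sides (for the interaction, up to 5 per direction with no overlap condition), up to 4 called members per list with the largest fold change, and the sort genes Il7r, Kit, Lilrb3 (which encodes PIR-B) and the most abundant Pira gene. Genes outside that rule are said to be chosen after their values were seen.

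The test was checked on data simulated for KO against wild type in PIR+, with 200 of 4542 genes changed in each of 10 sets. One simulation used library factors from the real data and a negative binomial size of 200, chosen so that the median simulated spread matched the real one. In it limma found 14.2% of 1.5-fold, 65.2% of 2-fold and 98.3% of 4-fold changes, and 1.25% of calls were false. With an assumed size of 8, a wider spread than the real one, it found 0.597%, 7.01% and 60.5%, and 2.81% of calls were false. With a size of 624 from gene-wise moments it found 16.1%, 70.0% and 97.9%, and 1.21% of calls were false. The assumed size came first and fell below a share set in advance as sufficient for 4-fold changes, after which the simulation was changed. camera found the changed list in 10 of 10 sets and called an unchanged list in 0 of 10, in each simulation. No correlation between the genes of a list was set in the simulations. These counts therefore cannot test list p-values at the preset correlation for genes that vary together. In the real libraries the estimated correlation ran from -0.044 (stem cell and multipotent progenitor list) to 0.606 (erythroid list). Within a simulation every gene had the same size, so genes with a wider spread of their own, such as the globins, were not represented. The shares of false calls need not hold for such genes.

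Alternatives covered median-of-ratios scaling, scaling to library totals, no filter, a stricter filter of 50, added constants of 0.1 and 10, limma voom with sample quality weights, a fit of only the groups compared, replicate number and source-name day as added terms, the 6 libraries whose markers field matches the title, a fold of at least 2, and leaving out each library. Leaving out the 5 libraries with Hba-a1 above 100 was added after the values were seen. Scaling to spike-in totals and the DESeq2 test were planned and not run, because the table has no spike-in rows and its values are not whole counts.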

Results

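PIR, the paired immunoglobulin-like receptor, is encoded by the Pira genes and by Lilrb3 (PIR-B). The libraries compare lineage-negative c-Kit+ fetal liver cells with and without it, in wild-type and KO mice. Values are normalized molecule counts as deposited, given as mean ± SD with n = 3 unless stated. Pira2 (chromosome 7, 3836812 to 3845051, GRCm38) was 32.3 ± 3.81 in PIR+ wild-type and 15.9 ± 7.53 in PIR+ KO libraries. Pira1 was 14.0 ± 3.04 and 8.27 ± 4.01, and Lilrb3 was 11.7 ± 2.42 and 9.07 ± 3.01. All 3 were listed at 0 in the 6 PIR- libraries, so they follow the PIR sign of the titles and not that of the markers field. These genes resemble each other closely, and the assignment of reads among them is uncertain. Il7r, the interleukin-7 receptor gene, was present in every library. It was 16.9 ± 3.03 in PIR+ wild type, 18.9 ± 2.29 in PIR- wild type and 21.3 ± 4.55 in PIR- KO, and 9.7 to 16 in the 3 PIR+ KO libraries. Kit, which encodes the other sort marker, was 43.0 ± 9.40 in PIR+ and 21.1 ± 3.91 in PIR- wild-type libraries. In KO libraries it was 46.1 ± 9.44 and 25 ± 8.33.

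PIR+ libraries had higher sums than PIR- libraries. Their summed values were 237066 ± 29010 against 180810 ± 24473 in PIR- libraries (n = 6 each), a ratio of 1.31 (exact two-sided permutation p = 0.00649, 924 permutations). More genes were above 0 in them, 11042 ± 128 against 10392 ± 266 (exact permutation p = 0.00216). Sums of KO and wild-type libraries were 219954 ± 40097 and 197922 ± 37951, a difference this test did not call (exact permutation p = 0.355). Globin messages stood out in 5 libraries. Hba-a1, an adult alpha globin gene, was 359.6 in PIR+ wild-type replicate 3 and 481.4 and 604.1 in PIR- wild-type replicates 2 and 3. It was 377.7 in PIR+ KO replicate 1 and 547.3 in PIR- KO replicate 1. It was 62.6 in PIR- wild-type replicate 1 and 8.2 to 18.0 in the other 6. Log values correlated across genes at r = 0.935 to 0.959 within a group and 0.781 to 0.946 between groups, so the ranges overlap. Genes are not independent replicates in these correlations.

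**Figure D1:**
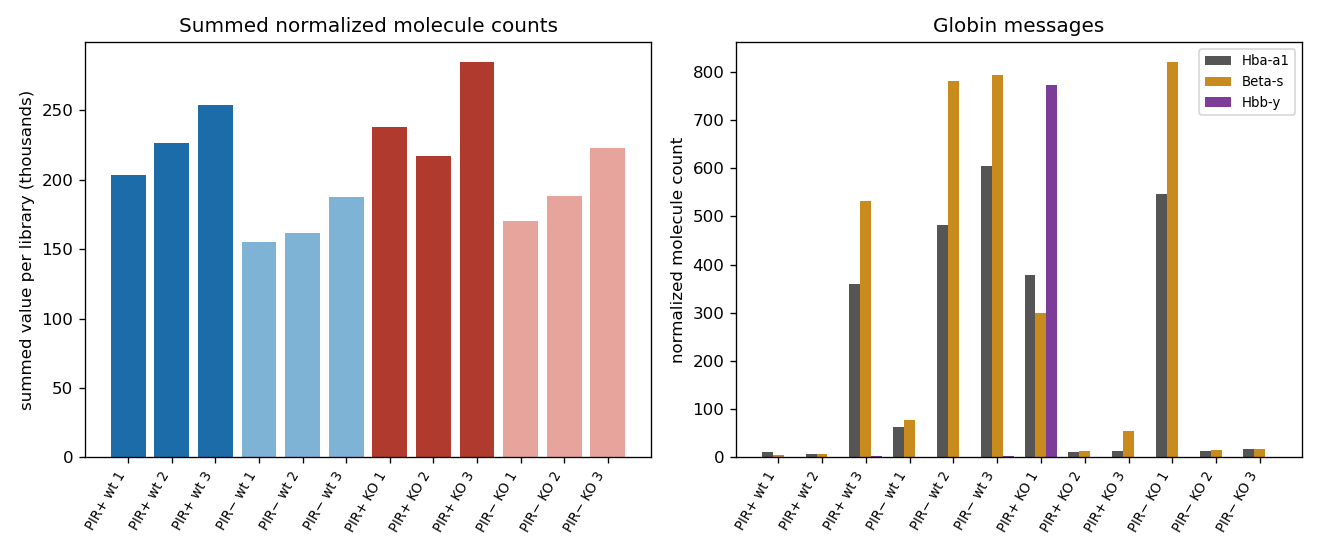
Left, the summed normalized molecule count of each of the 12 libraries, with PIR+ libraries in dark and PIR- libraries in light colours (blue wild type, red KO). Right, the values of 3 globin genes per library as bars: 5 libraries have Hba-a1 above 100, and the embryonic gene Hbb-y is high in 1 of them, PIR+ KO replicate 1.

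In wild-type cells, the messages of early B-cell development were concentrated in the PIR- subset. Igll1 (chromosome 16, 16860671 to 16863985), a surrogate light chain gene of the pre-B-cell receptor, was 269 ± 37.7 in PIR- and 0.867 ± 0.961 in PIR+ libraries. Its log2 fold change, PIR+ over PIR-, was -7.30 ± 0.28 (SE, adjusted p = 1.14e-43). Vpreb1, the partner of Igll1, was 114 ± 21.4 against 0.233 ± 0.404 (-6.58 ± 0.32, adjusted p = 6.54e-35). Cd79a, a signalling chain of the B-cell receptor, was 219 ± 38.1 against 5.83 ± 3.10 (-5.10 ± 0.27, adjusted p = 3.29e-32). Pou2af1, a B-cell transcription coactivator, was 67.8 ± 13 in PIR- and 1.30 ± 1.68 in PIR+ libraries. Of the 14 tested B-lineage genes, 13 were lower in PIR+ cells and 1 was higher, the same counts when adjusted over the list alone. The camera adjusted p was 1.33e-58, and adjusted p = 0.000309 with an estimated correlation. The 1 that was higher, Bank1, chosen after its value was seen, was not called after median-of-ratios scaling. Lef1, a transcription factor of lymphocyte development, was also lower in PIR+ cells, 0.433 ± 0.751 against 44.8 ± 4.92. Vpreb1 has a near-identical paralog, Vpreb2, with which reads can be confused.

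PIR+ wild-type cells were higher for the tested stem and progenitor genes and myeloid genes. Cd34 (chromosome 1, 194938819 to 194961279), a progenitor surface protein, was 153 ± 19.8 in PIR+ and 6.03 ± 1.74 in PIR- libraries. Its log2 fold change was 4.47 ± 0.21 (SE, adjusted p = 1.85e-35). Of the 20 genes of the stem cell and multipotent progenitor list 6 were tested. All 6 were higher, also when adjusted over the list alone (adjusted p = 0.0018 with an estimated correlation). Among them, Mycn was 32.2 ± 4.21 against 1.53 ± 1.33 and Lmo2 was 26.0 ± 7.60 against 3.90 ± 0.70. Hlf, a transcription factor of stem cells, was 6.07 ± 2.98 in PIR+ and listed at 0 in PIR- libraries. Of 22 neutrophil and monocyte genes 5 were tested. All 5 were higher, also over the list alone, and 4 of them on both scales (adjusted p = 0.0303 with an estimated correlation). A gene near 0 in PIR- cells is tested only if it is high in PIR+ cells, so the filter set the direction for such genes. Csf1r (chromosome 18, 61100598 to 61132149), the receptor of macrophage colony-stimulating factor, was 23.6 ± 2.70 against 0.633 ± 0.569. Mpo, myeloperoxidase, was 56.9 ± 9.70 against 6.83 ± 5.14, and Sfpi1, which encodes PU.1, was 51.9 ± 5.40 against 8.93 ± 1.2. Tyrobp, an adaptor of activating receptors in myeloid and NK cells, was 104 ± 20.4 against 3.47 ± 3.95.

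Lymphoid progenitor genes mostly followed the same direction. Of 17 tested, 11 were higher in PIR+ wild-type cells and 4 lower (12 and 4 adjusted over the list alone; adjusted p = 0.365 with an estimated correlation). Flt3 (chromosome 5, 147330741 to 147400489), a receptor of early lymphoid progenitors, was 73.7 ± 11.3 against 6.27 ± 3.20. Ccr9 (chromosome 9, 123678439 to 123784330), a chemokine receptor of thymus-seeding cells, was 65.8 ± 10.8 against 2.17 ± 1.51. Rag1, Rag2 and Tcf3, chosen here after their values were seen, are among the 4 that were lower. Id2, an inhibitor of E proteins required by innate lymphoid cells, was 54.2 ± 17.6 against 0.80 ± 0.80. Cd7, a surface protein of T, NK and lymphoid progenitor cells, was 18.5 ± 3.39 against 0.267 ± 0.462. Of 10 receptor genes 8 were higher and 1 lower, the same when adjusted over the list alone (adjusted p = 0.0551 with an estimated correlation). Of 6 genes of the fetal Lin28b program 5 were higher and 1 lower, the same over the list alone (adjusted p = 0.137 with an estimated correlation). Hmga2, a chromatin protein of fetal progenitors, was 136 ± 34.0 against 14.8 ± 4.86, and Arid3a was 63.8 ± 4.44 against 14.4 ± 3.93. The imprinted RNA H19 was the lower one, 84.6 ± 8.86 against 261 ± 77.5.

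The 3 D cyclins parted. Ccnd1 (61.0 ± 8.31 against 5.23 ± 2.38) and Ccnd2 (67.0 ± 14.6 against 10.4 ± 5.90) were higher in PIR+ wild-type cells, and Ccnd3 (42.0 ± 1.80 against 196 ± 38.5) was lower. Of 25 cell cycle genes 7 were higher and 8 lower, the same over the list alone, and 2 and 13 after median-of-ratios scaling (adjusted p = 0.226 with an estimated correlation). Of 7 erythroid genes 5, all globins, were lower in PIR+ (1 higher and 5 lower adjusted over the list alone; adjusted p = 0.0551 with an estimated correlation). The globin-rich libraries include 2 of the 3 PIR- and 1 of the 3 PIR+ wild-type libraries. Of the 5 tested sort markers 4 were higher and 0 lower, the same over the list alone (adjusted p = 0.0551 with an estimated correlation). The sort itself sets the direction of this list.

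In all, limma called 2015 of 4542 genes between the wild-type subsets, 1846 higher and 169 lower in PIR+ (91.6% higher). In 2362 genes (52.0%) the 3 and 3 libraries did not overlap, where chance gives 10%. The median gene was 0.51 (log2) higher in PIR+ on the deposited scale and 0.02 after median-of-ratios scaling. Scaling called 1025 genes, 524 higher and 501 lower relative to the median gene. On both scales 524 were higher and 168 lower. The authors' DESeq2 p-value was under 0.05 for 593 of the 2015 genes and for 839 of the 1025. Without PIR+ wild-type replicate 3 the count was 1320. Without the 5 globin-rich libraries, which leaves 1 PIR- wild-type library, it was 700. Kit passed on the deposited scale (0.99 ± 0.23 SE, adjusted p = 0.000427) and not after scaling (0.49, adjusted p = 0.0532), with a range of 5.19e-05 to 0.0557 over all alternatives. Il7r did not pass on the deposited scale (-0.16 ± 0.27, adjusted p = 0.624) and passed after scaling (-0.65, adjusted p = 0.031), with a range of 0.031 to 0.878.

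In KO cells, B-lineage genes and stem and multipotent progenitor genes again separated the subsets. Igll1 was 227 ± 46.2 in PIR- and listed at 0 in PIR+ KO libraries. Vpreb3 was 107 ± 19.8 against 0.40 ± 0.693, and Cd79a was 190 ± 66.6 against 0.333 ± 0.577 (adjusted p = 1.62e-44). Of 14 B-lineage genes 12 were lower and 1 higher in PIR+, the same over the list alone (adjusted p = 0.000157 with an estimated correlation). Cd34 was 182 ± 25.6 against 19.8 ± 1.30, a log2 fold change of 3.13 ± 0.21 (SE, adjusted p = 2.36e-24). Of 6 stem and multipotent progenitor genes 5 were higher (6 adjusted over the list alone; adjusted p = 0.00099 with an estimated correlation), with Hlf at 16.9 ± 3.79 against 0.567 ± 0.981. Of 5 neutrophil and monocyte genes 4 were higher, 2 of them on both scales (5 adjusted over the list alone; adjusted p = 0.187 with an estimated correlation). Csf1r was 30.8 ± 17.5 against 6.03 ± 2.04. Mpo, at 47.8 ± 8.22 against 22.5 ± 8.36, was not called after scaling (fold change 0.72, adjusted p = 0.138, with a range of 4.02e-05 to 0.138 over all alternatives).

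Ccr9 was 21.6 ± 5.14 in PIR+ and 2.77 ± 2.25 in PIR- KO libraries (2.76 ± 0.34 SE, adjusted p = 6.19e-11). Id2 was 20.1 ± 6.99 against 0.90 ± 0.794 (3.53 ± 0.38, adjusted p = 4.46e-13). Ctla2a, a protease inhibitor gene, was 35.2 ± 1.53 against 2.37 ± 1.1. Of 17 lymphoid progenitor genes 11 were higher and 4 lower (12 and 4 over the list alone; camera adjusted p = 0.294). Il7r was among the lower ones (-0.73 ± 0.27, adjusted p = 0.0332). Without PIR+ KO replicate 1 or 2 its adjusted p was 0.159 and 0.0643, and without PIR- KO replicate 1 or 3 it was 0.15 and 0.0757 (fold changes -0.71 to -0.58), with a range of 0.000439 to 0.612 over all alternatives. Of 10 receptors 8 were higher and 2 lower, the same over the list alone (adjusted p = 0.203 with an estimated correlation). Of 6 fetal Lin28b program genes 5 were higher and 1 lower, also over the list alone (camera adjusted p = 0.294), and the lower one was again H19 (57.4 ± 14.9 against 336 ± 108). Of 25 cell cycle genes 3 were higher and 1 lower, and 1 and 10 after scaling (2 and 1 over the list alone; adjusted p = 0.495 with an estimated correlation). Their median was 0.02, while camera gave a lower direction relative to all genes. Of 7 erythroid genes 1 was higher and 1 lower, the same over the list alone (camera adjusted p = 0.0705, a lower direction with a median of 0.01). Car2, carbonic anhydrase 2, was higher (33.3 ± 6.70 against 11.2 ± 4.95), and Tfrc, the transferrin receptor, was lower (15 ± 4.78 against 35.0 ± 5.40), with an adjusted p of 4.77e-07 to 0.126 over all alternatives. Of 5 sort markers 4 were higher and 1 lower, as over the list alone (adjusted p = 0.162 with an estimated correlation).

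limma called 1158 genes between the KO subsets, 1023 higher and 135 lower in PIR+ (88.3% higher). In 1776 genes (39.1%) the libraries did not overlap, where chance gives 10%. The median gene was 0.39 (log2) higher in PIR+, and scaling called 710 genes, 369 higher and 341 lower, with 369 and 135 on both scales. The count was 662 without PIR+ KO replicate 3, 720 without PIR- KO replicate 1 and 576 without the globin-rich libraries. Across the 4542 genes, the subset effects in wild type and in KO correlated at r = 0.837 (rho = 0.644). The calls shared 802 higher and 110 lower genes, where independent draws give 416 and 5.02. Averaged over genotypes, 2706 genes were called, 2498 higher and 208 lower in PIR+ (92.3% higher, median 0.45), of which 698 and 204 held on both scales. Of 919 genes called on both scales, 902 had the same sign on each, and the rest changed sign. Cd34 was higher in that average by 3.80 ± 0.15 and Id2 by 4.26 ± 0.27 (log2 ± SE), and the fold change of Cd79a was -6.15 ± 0.19. In it 914 genes (20.1%) separated 6 PIR+ from 6 PIR- libraries without overlap, where chance gives 0.216%.

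**Figure D2:**
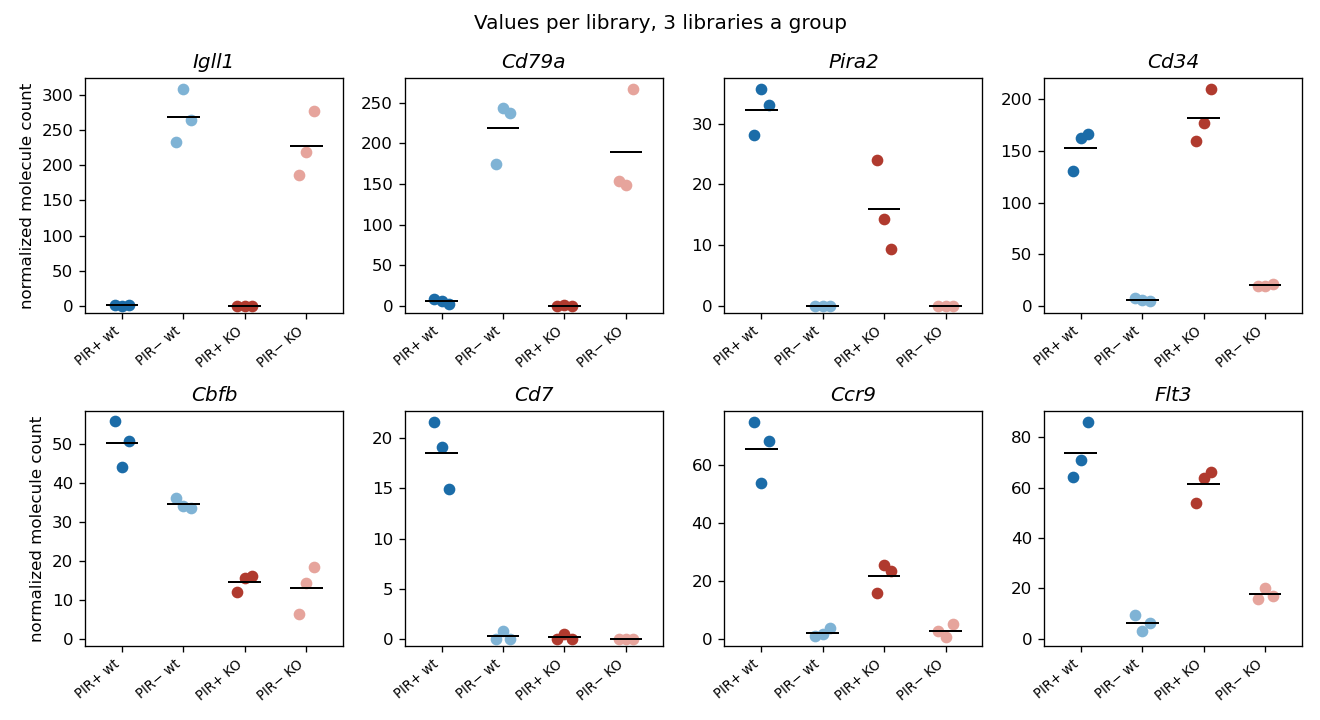
Normalized molecule counts of 8 genes in each library (points, 3 per group) with the group mean as a line. Igll1 and Cd79a lie near 0 in PIR+ libraries, Pira2 is listed at 0 in PIR- libraries, Cd34 is 153 and 182 on average in PIR+ wild type and KO, and Cbfb averages 50.2 and 34.5 in wild-type against 14.6 and 13.1 in KO libraries.

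In PIR+ cells, KO libraries had less message of Cd7, Ccr9, Ifitm1, Cbfb and Crip1. Cd7 (chromosome 11, 121036747 to 121039418) fell from 18.5 ± 3.39 in wild type to 0.167 ± 0.289 in KO. Its log2 fold change was -4.08 ± 0.64 (SE, adjusted p = 2.61e-06), a value that depends on the added constant. With a constant of 0.1 Cd7 was not called (adjusted p = 0.344, the highest of a range from 7.71e-18). Ccr9 fell from 65.8 ± 10.8 to 21.6 ± 5.14 (-1.57 ± 0.34, adjusted p = 0.00226). Ifitm1 (chromosome 7, 140967221 to 140969825), an interferon-inducible membrane protein gene, fell from 52.8 ± 5.95 to 12.4 ± 7.08 (-2.20 ± 0.34, adjusted p = 2.28e-06). Cbfb (chromosome 8, 105170674 to 105217989), which encodes the partner subunit of the Runx transcription factors, fell from 50.2 ± 5.87 to 14.6 ± 2.17 (-1.72 ± 0.25, adjusted p = 6.65e-07). Crip1 (chromosome 12, 113146316 to 113153879), a LIM protein gene, fell from 92.7 ± 6.52 to 21.1 ± 3.82 (-2.09 ± 0.19, adjusted p = 5.47e-15). Ccnd2 fell from 67.0 ± 14.6 to 26.0 ± 10.4, and Gsn (gelsolin) fell from 30.8 ± 3.20 to 10 ± 2.58. Tsc22d1, a transcription regulator, fell from 43.9 ± 4.45 to 13.5 ± 7.95.

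Other genes rose in PIR+ KO cells. Gimap4 (chromosome 6, 48684549 to 48692060), a lymphocyte GTPase, rose from 16.3 ± 4.81 to 58.9 ± 6.93 (1.83 ± 0.28 SE, adjusted p = 1.32e-06). Pnp (chromosome 14, 50931082 to 50965237), purine nucleoside phosphorylase, rose from 75.9 ± 8.61 to 198 ± 23.3 (1.37 ± 0.18, adjusted p = 2.56e-08). Pnp has a close paralog, Pnp2, with which reads can be confused. Tspan6 rose from 5.73 ± 1.68 to 23.9 ± 4.32, Ctla2a from 9.57 ± 1.5 to 35.2 ± 1.53, and Egfl7, an endothelial and progenitor gene, from 64.3 ± 8.84 to 136 ± 27.4. Ctla2a was not called with an added constant of 0.1 (adjusted p = 0.311) or in the 6 libraries whose markers field matches the title (0.104), in a range of 1.33e-09 to 0.311. Tspan6 lies on chromosome X (133891068 to 133898429), and sex-linked messages, chosen after their values were seen, also differed between these groups. Xist, expressed from the inactive X chromosome, was 12.7 to 18.4 in PIR+ wild-type and 31.3 to 34.2 in PIR+ KO libraries, and Ddx3y, a gene of the Y chromosome, was 5.4 to 7.9 and 0.8 to 2.0. Of 14 B-lineage genes 2 fell from levels already low (3 over the list alone; adjusted p = 0.123 with an estimated correlation). They were Cd79a (5.83 ± 3.10 to 0.333 ± 0.577) and Vpreb3 (2.17 ± 1.97 to 0.40 ± 0.693). Vpreb3 was called neither after scaling (adjusted p = 0.136) nor without any 1 of 7 libraries. Without PIR+ wild-type replicate 1 its adjusted p was 0.911, without PIR- wild-type replicate 1 it was 0.0567, and without PIR+ KO replicate 2 or 3 it was 0.255 and 0.332. Without PIR- KO replicate 1, 2 or 3 it was 0.0869, 0.0747 and 0.0906, in a range of 0.0014 to 0.911 over all alternatives. Its fold change was -1.11, and -1.11 to -0.64 in these 7.

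Of 6 stem and multipotent progenitor genes 1, Cd48, rose in PIR+ KO cells, from 12.7 ± 5.54 to 31.1 ± 3.75 (2 over the list alone; adjusted p = 0.0706 with an estimated correlation). Cd48 was not called after scaling (adjusted p = 0.0557) or without PIR+ wild-type replicate 1 (0.108), PIR+ wild-type replicate 3 (0.0933) or PIR+ KO replicate 2 (0.0744), in a range of 0.000163 to 0.146, with fold changes of 1.14 to 1.21 without these libraries against 1.29. Of 10 receptors 1, Ccr9, fell, as over the list alone (adjusted p = 0.182 with an estimated correlation). Ccr9 was also the 1 of 17 lymphoid progenitor genes that fell, as over the list alone (camera adjusted p = 0.106). Of 25 cell cycle genes 1, Ccnd2, fell, as over the list alone, while camera gave the list a higher direction (adjusted p = 0.47 with an estimated correlation). None of 5 neutrophil and monocyte genes was called, none over the list alone (camera adjusted p = 0.166). None of 6 fetal program genes was called (1 lower over the list alone; camera adjusted p = 0.145). Of 7 erythroid genes 1 fell (1 higher and 1 lower over the list alone; camera adjusted p = 0.917, a lower direction with a median of 0.34). It was Tfrc, whose call ended without PIR+ wild-type replicate 1, 2 or 3 (0.296, 0.0501 and 0.178), PIR+ KO replicate 1 or 2 (0.323 and 0.288) or PIR- KO replicate 2 (0.0603), in a range of 0.00469 to 0.573. The fold change of Tfrc was -0.88, and -1.01 to -0.74 without these libraries. No sort marker was called, none over the list alone (adjusted p = 0.123 with an estimated correlation). Pira2 had a fold change of -1.07 ± 0.45 (adjusted p = 0.515).

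limma called 41 genes between KO and wild type in PIR+, 20 higher and 21 lower (48.8% higher, 313 at an unadjusted p under 0.05). In 503 genes (11.1%) the libraries did not overlap, where chance gives 10%. The median gene was 0.09 (log2) higher, scaling called 46 genes, 17 higher and 29 lower, and 13 and 18 held on both scales. Without the globin-rich libraries 27 genes were called, and Ccnd2 (-1.04 against -1.38 in all libraries, adjusted p = 0.0887) and Ccr9 (-1.34, adjusted p = 0.0614) were not among them. Ccr9 also missed the threshold without PIR+ wild-type replicate 1 (-1.48, 0.0523) and Tsc22d1 without PIR+ KO replicate 2 (-1.36 against -1.77, 0.0602). Over all alternatives the ranges were 1.38e-07 to 0.295 for Ccnd2, 1.04e-09 to 0.134 for Ccr9, 8.96e-10 to 0.212 for Tsc22d1, 1.27e-06 to 0.184 for Gsn and 6.58e-17 to 0.0879 for Cd79a. The authors' p-value was under 0.05 for 39 of the 41 genes.

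In PIR- cells, KO libraries had more of several progenitor and myeloid genes that were higher in PIR+ than in PIR- wild-type cells. Cd34 rose from 6.03 ± 1.74 in wild type to 19.8 ± 1.30 in KO (log2 fold change 1.59 ± 0.21 SE, adjusted p = 6.1e-08). Hmga2 (chromosome 10, 120361275 to 120476469) rose from 14.8 ± 4.86 to 55.1 ± 10.3 (1.87 ± 0.21, adjusted p = 9.93e-11). Ccnd1 rose from 5.23 ± 2.38 to 15.3 ± 3.12 (1.44 ± 0.25, adjusted p = 2.57e-05). Flt3 rose from 6.27 ± 3.20 to 17.7 ± 2.25 and Egfl7 from 18.9 ± 4.47 to 47.2 ± 9.24. Cbfb fell from 34.5 ± 1.35 to 13.1 ± 6.11 (-1.45 ± 0.25, adjusted p = 3.79e-05). Crip1 fell from 205 ± 26.5 to 107 ± 25, and Lgals1 (galectin-1) fell from 72.3 ± 5.16 to 34.4 ± 7.51.

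Of 5 neutrophil and monocyte genes 2 rose on both scales (4 adjusted over the list alone; adjusted p = 0.028 with an estimated correlation). They were Csf1r (0.633 ± 0.569 to 6.03 ± 2.04) and Mpo (6.83 ± 5.14 to 22.5 ± 8.36). Of 6 stem and multipotent progenitor genes 2 rose on both scales (3 over the list alone; adjusted p = 0.0136 with an estimated correlation). They were Cd34 and Cd48 (4.37 ± 2.34 to 18.4 ± 4.86). Of 6 fetal program genes 1, Hmga2, rose (3 over the list alone; adjusted p = 0.0614 with an estimated correlation). Of 17 lymphoid progenitor genes 2, Flt3 and Mef2c, rose (5 over the list alone; camera adjusted p = 0.0767). Mef2c (0.84) was not called without PIR- KO replicate 2 (0.82, adjusted p = 0.0525) or the globin-rich libraries (0.75, adjusted p = 0.289), in a range of 0.000489 to 0.289. Flt3 and Csf1r are also the 2 of 10 receptors that rose, as over the list alone (adjusted p = 0.348 with an estimated correlation). None of the 14 B-lineage genes was called, none over the list alone, with a median of -0.22 (adjusted p = 0.185 with an estimated correlation). Igll1, for example, was 269 ± 37.7 in wild type and 227 ± 46.2 in KO. Of 25 cell cycle genes 1, Ccnd1, rose, as over the list alone (camera adjusted p = 0.954). No sort marker was called, none over the list alone (camera adjusted p = 0.357). Of 7 erythroid genes 4, all globins, were lower in KO on the deposited scale (5 over the list alone; adjusted p = 0.028 with an estimated correlation) and none was after scaling. The globin-rich libraries include 2 of the 3 wild-type and 1 of the 3 KO libraries of this subset. Hba-a1 was not called without PIR- KO replicate 2 or 3 (adjusted p = 0.41 and 0.663) or PIR+ KO replicate 3 (0.121), in a range of 3.25e-07 to 0.675, with fold changes of -2.28 to -1.38 against -2.28.

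limma called 59 genes in PIR- cells, 49 higher and 10 lower in KO (83.1% higher, 629 at an unadjusted p under 0.05). In 700 genes (15.4%) the libraries did not overlap, where chance gives 10%. The median gene was 0.20 (log2) higher, scaling called 77 genes, 47 higher and 30 lower, and 39 and 5 held on both scales. The count was 37 without PIR- KO replicate 2 and 33 without PIR- KO replicate 3. Without the globin-rich libraries 1 wild-type and 2 KO libraries are left in this subset. The spread then comes from groups with more than 1 library, so which genes pass depends on the other libraries in the fit. Fold changes were then 1.23 for Cd34, 1.61 for Hmga2, 1.64 for Ccnd1 and 1.48 for Egfl7. Cbfb (fold change -1.10, adjusted p = 0.163), Crip1 (-0.58, 0.425), Lgals1 (-0.79, 0.287) and Flt3 (0.89, 0.259) were then not called. Nor were Csf1r (1.59, 0.0747), Mpo (0.60, 0.463) and Cd48 (1.27, 0.124). Over all alternatives, the adjusted p was 5.31e-06 to 0.163 for Cbfb and 1.81e-10 to 0.463 for Mpo, the gene of these 7 with the highest value. For Ccnd1 it was 2.65e-07 to 0.0532.

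The KO effects in the PIR+ and PIR- subsets correlated weakly across genes (r = 0.127, rho = 0.0844, 4542 genes). Few of these genes were called (41 and 59), and noise in the others lowers r, which was not allowed for. The low r therefore does not show that the KO effects differ between the subsets. The calls still shared 5 higher genes, Cd48, Egfl7, Eltd1 and Erdr1 among them, where independent draws give 0.216. They shared 3 lower genes, Cbfb, Crip1 and Lgals1, where independent draws give 0.0462. In 1 of the subsets, Erdr1, Eltd1 and Lgals1 fall outside the naming rule and were chosen after their values were seen. In PIR+ cells the adjusted p of Eltd1 was 1.23e-05 to 0.619 over all alternatives. Averaged over subsets, 81 genes were called, 68 higher and 13 lower in KO (84.0% higher, 660 at an unadjusted p under 0.05, median 0.15), of which 55 and 12 held on both scales. In that average Cbfb fell by 1.58 ± 0.18 (log2 ± SE, adjusted p = 6.53e-11) and Crip1 fell by 1.52 ± 0.14 (adjusted p = 1.13e-15). Egfl7 rose by 1.17 and Cd48 by 1.61. Of 6 stem and multipotent progenitor genes 2 rose (4 over the list alone; adjusted p = 0.0062 with an estimated correlation). The count was 51 without PIR+ KO replicate 3 and 138 without PIR- KO replicate 1. In the average 10 genes (0.22%) separated 6 from 6 libraries, where chance gives 0.216%.

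**Figure D3:**
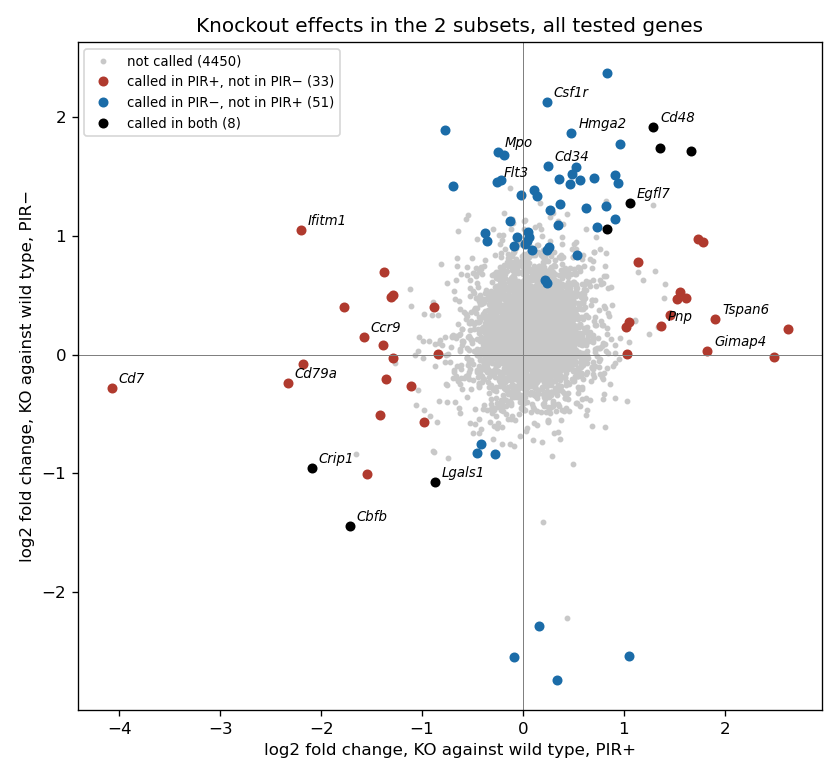
Log2 fold change of KO over wild type in PIR+ cells (horizontal) and in PIR- cells (vertical) for all 4542 tested genes, as points coloured by the comparison in which a gene was called. Of the called genes 8 were called in both subsets, Cbfb, Crip1 and Lgals1 among them at the lower left.

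The KO effect differed between the subsets for 26 genes by the test of the interaction, 5 with a higher and 21 with a lower effect in PIR+ than in PIR- cells. The sex-linked messages of PIR+ KO libraries differed from those of the other groups, so sex may contribute to these differences, which was not tested. Ifitm1 fell in PIR+ cells and was 2.33 ± 0.751 in wild-type and 6.47 ± 4.05 in KO PIR- cells (difference -3.25, adjusted p = 4.74e-06). Cd34, Flt3 and Hmga2, which rose in PIR- cells, differed by -1.34, -1.72 and -1.39. Gimap4 and Pnp, which rose in PIR+ cells, differed by 1.80 and 1.13. Of 5 neutrophil and monocyte genes 2, Mpo and Csf1r, had a lower difference (3 over the list alone; adjusted p = 0.0683 with an estimated correlation). Of 7 erythroid genes 1, Beta-s, had a higher and 1, Tfrc, a lower difference (6 and 1 over the list alone; adjusted p = 0.0683 with an estimated correlation). Of 6 fetal program genes 1 was lower (4 over the list alone; adjusted p = 0.0683 with an estimated correlation). Of 10 receptors 2 were lower (4 over the list alone; adjusted p = 0.075 with an estimated correlation). Of 17 lymphoid progenitor genes 1 was lower (4 over the list alone; adjusted p = 0.342 with an estimated correlation). The other 4 lists were not called by camera.

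Of these differences 19.2% were higher, 250 genes had an unadjusted p under 0.05, and 4 higher and 17 lower differences held on both scales, with a median of -0.13. The count was 15 without PIR+ wild-type replicate 2 and 6 without the globin-rich libraries, where Ifitm1 and Cd79a were still called. Cd34 (-0.82), Flt3 (-0.95) and Hmga2 (-0.81, adjusted p = 0.998 each), Gimap4 (1.21, 0.971) and Pnp (1.24, 0.396) were then not called. Cd34 also missed the threshold without PIR+ wild-type replicate 2 (0.0573) or PIR+ KO replicate 1 (0.06), with differences of -1.29 to -1.25. Hmga2 missed it without PIR- wild-type replicate 2 (-1.10, 0.0512) and Gimap4 without PIR+ wild-type replicate 3 (1.54, 0.0513). Over all alternatives, the adjusted p of Ifitm1 was 2.28e-10 to 0.0484, and that of Cd79a reached 0.99 with an added constant of 10. That of Pnp was 1.44e-05 to 0.396, and Cd34, Flt3, Hmga2 and Gimap4 each reached 1 in the 6 libraries whose markers field matches the title.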

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

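The tests of receptor molecules, of a smaller B-lineage share and of the globin-rich libraries in this part were chosen only after the result was seen, and the splits of the samples were set beforehand. The genes below were singled out because the KO effect in PIR+ cells differed from that in PIR- cells by the interaction test (log2 difference, adjusted p under 0.05). In PIR+ cells the KO effect was lower for Ifitm1 (-3.25), Cd7 (-3.80), Cd79a (-2.09), Ccnd2 (-2.07), Tsc22d1 (-2.17), Trp53i11 (-2.11) and Tfrc (-1.29). It was also lower for Cd34 (-1.34), Flt3 (-1.72), Hmga2 (-1.39), Mpo (-1.95), Csf1r (-1.89), Ncf1 (-2.67) and Ifitm3 (-2.12). It was higher for Gimap4 (1.80), Pnp (1.13), Tspan6 (1.61) and Beta-s, a beta globin gene (3.59). After median-of-ratios scaling Csf1r (-1.94, adjusted p = 0.071), Tsc22d1 (-2.11, 0.0626) and Beta-s (3.69, 0.561) no longer passed.

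Trp53i11, a p53-induced gene, was 5.27 ± 1.79 in PIR+ wild type and 0.367 ± 0.321 in PIR+ KO, and 62.6 ± 8.18 and 60.4 ± 16.6 in the PIR- groups (mean ± SD, n = 3). Ncf1, a subunit of the phagocyte oxidase, was 52.1 ± 11.5 and 30.2 ± 7.55 in PIR+ and 0.90 ± 1.56 and 4.80 ± 0.872 in PIR- cells. Cd7 was near 0 in all groups but PIR+ wild type, so its difference was set by that group. Cd7 missed the threshold without PIR+ wild-type replicate 1 or 2 (adjusted p = 0.0944 and 0.0644). Ifitm3 missed it without PIR+ wild-type replicate 2 or 3 (0.0587 and 0.131) or PIR- KO replicate 3 (0.0606). Tsc22d1 missed it without PIR- wild-type replicate 2 (0.082), PIR+ KO replicate 2 (0.114) or PIR- KO replicate 3 (0.08). Beta-s missed it without PIR+ wild-type replicate 1 or 2 (0.409 and 0.143), PIR+ KO replicate 3 (0.212) or PIR- KO replicate 2 or 3 (0.263 and 0.702). Csf1r missed it without PIR+ wild-type replicate 1, 2 or 3 (0.114, 0.0693 and 0.145), PIR- wild-type replicate 3 (0.0987), PIR+ KO replicate 1 or 2 (0.216 and 0.307) or PIR- KO replicate 1 or 2 (0.129 and 0.174). Tfrc missed it without PIR+ wild-type replicate 1, 2 or 3 (0.165, 0.0573 and 0.143) or PIR- wild-type replicate 1, 2 or 3 (0.095, 0.0512 and 0.0783). Tfrc also missed it without PIR+ KO replicate 1 or 2 (0.209 and 0.212) or PIR- KO replicate 1 or 3 (0.129 for each). Tspan6 missed it without PIR+ wild-type replicate 1 (0.165), PIR- wild-type replicate 2 or 3 (0.0846 and 0.0556), any of PIR+ KO replicates 1, 2 and 3 (0.06, 0.0518 and 0.105) or PIR- KO replicate 1 or 3 (0.0824 and 0.0741). In all losses of an interaction call without a single library the difference was 67.5% to 110% of the main value. Over all alternatives the highest adjusted p was 0.908 for Cd7, 0.883 for Beta-s, 0.847 for Tspan6 and 1 for Ifitm3, Tsc22d1, Csf1r and Tfrc. The lowest ran from 1.31e-19 for Beta-s to 0.00962 for Tspan6. Without the globin-rich libraries 1 PIR- wild-type library is left, replicate 1, which still held globin messages (Hba-a1 62.6, Beta-s 77.4). On the PIR- wild-type side the Beta-s difference then rests on that library alone. Of all genes singled out here, those other than Ifitm1, Cd79a and Beta-s were not called without the globin-rich libraries. Then differences about as large as in all libraries were left for Trp53i11 (-2.28, adjusted p = 0.147), Cd7 (-4.12, 0.198), Tsc22d1 (-1.94, 0.233), Pnp (1.24, 0.396), Tspan6 (1.48, 0.847) and Tfrc (-1.14, 0.975). They were smaller for Ifitm3 (-1.54, 0.847), Gimap4 (1.21, 0.971), Ccnd2 (-1.14, 0.965) and, at 0.998 each, Ncf1 (-1.19), Mpo (-0.70), Csf1r (-1.10), Cd34 (-0.82), Flt3 (-0.95) and Hmga2 (-0.81). Over all alternatives the highest adjusted p was 0.936 for Trp53i11, 0.396 for Pnp and 1 for Gimap4, Ccnd2, Ncf1, Mpo, Cd34, Flt3 and Hmga2.

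The real interaction gave 26 genes, and 4 of 100 splits of the samples, out of 200 possible, gave as many, the real one included. The splits exchanged genotypes within each subset, so they stand for no KO effect in either subset. They cannot test whether the KO effects differ between the subsets, and chance is not excluded for the interaction. The highest of the other splits gave 95 genes, several times the real count. It kept the PIR- genotypes and set PIR+ wild-type replicates 1 and 2 and PIR+ KO replicate 2 against the other 3 PIR+ libraries, which points to a structure of the samples. The first 3 have the lowest summed values of the PIR+ libraries, 203135 to 226562 against 237628 to 284648. Whether the sums raise the count was not tested. Because this split keeps the real PIR- genotypes, the KO effect in PIR- cells (59 genes by itself) adds to its count, and no other structure was tested. For KO against wild type averaged over subsets, 2 of 100 splits gave as many as the real 81, with 95 as the highest other, and for PIR+ against PIR- averaged over genotypes 1 of 100 splits gave as many as the real 2706, with 361 as the highest other. For PIR+ against PIR- averaged over genotypes, chance can be excluded at the 0.05 level. For the KO average the share is also under 0.05, but the split with 95 genes called more than the real one. That split grouped the PIR+ libraries as the highest split of the interaction did and kept the PIR- genotypes. A structure of the samples therefore stays open for the KO average. Genes without overlap in that average were at the chance rate (0.22% against 0.216%). In each of the 4 comparisons of 3 against 3 libraries, 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Their real counts were 2015, 1158, 41 and 59, and the highest others 0, 0, 5 and 5, for the subsets in wild type and in KO and for the KO effect in PIR+ and in PIR-.

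The pattern most open to follow-up is the set of 39 genes, Cd34, Flt3, Hmga2, Mpo and Csf1r among them, that rose in PIR- KO cells on both scales. PIR+ cells in the PIR- KO tubes would need a median RNA share of 28.3%, which implies 46.9 molecules of Pira1, Pira2 and Lilrb3, and 0 were seen. The tubes were sorted on this receptor, so the count speaks only to cells with receptor message. It cannot exclude cells that resemble PIR+ cells but lack that message. Without the globin-rich libraries the median log2 fold change of the 39 genes was 1.23 against 1.42 in all libraries. Single genes then ran from 0.12 (Tyrobp, 1.69 in all libraries) to 2.71 (Eltd1, 1.74). Of the 5 named above, Cd34 was 1.23 against 1.59, Flt3 0.89 against 1.46, Hmga2 1.61 against 1.87, Mpo 0.60 against 1.71 and Csf1r 1.59 against 2.13. That fit leaves 1 wild-type and 2 KO libraries and the genes were chosen with these same libraries, so the globin-rich libraries stay open as a source. A smaller share of B-lineage cells in the PIR- KO tubes stays open, since the B-lineage list lay below all genes by -0.42 (difference of medians), and so does a shift within the PIR- cells of KO mice, which was not tested. Of the 39 genes, 32 were also higher in PIR+ than in PIR- wild-type cells on both scales (4.5 expected), a count that may be raised by the shared PIR- wild-type libraries. Simulated unchanged groups gave at most 1, but they held no changed genes and so cannot tell how far sharing raises the count. In KO cells 23 of the 39 were also higher in PIR+ than in PIR- cells (3.17 expected), where the shared libraries work against overlap.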

How the results depend on the processing

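The tests without the 5 globin-rich libraries, and those of voom, the markers field and single libraries for the correlations, were chosen only after the result was seen. All others were set before the data were examined. Of 244 alternatives for the main counts and correlations 181 stayed within 1.5 times the main count (for correlations, within their jackknife error) and 63 did not, and of 6720 for named genes 6025 kept their direction and side of the threshold, and 667 were weaker, 4 stronger and 24 reversed. Called genes are given in the order PIR+ against PIR- in wild type (2015 in the main test), in KO (1158) and averaged (2706), then KO against wild type in PIR+ (41), in PIR- (59) and averaged (81), then the interaction (26). Median-of-ratios scaling gave 1025, 710 and 1344 for the first 3 and library totals 1073, 725 and 1394, because both remove the higher sums of PIR+ libraries. The filter of 50 tests fewer genes and gave 537, 302, 632, 10, 22, 31 and 13. No filter gave 31 for KO in PIR-, 43 for the KO average and 3 for the interaction. voom gave 957 in wild type, 1402 in the average and 96 for KO in PIR+. A fold of at least 2 left 796, 558, 587 and, for the KO average, 33. An added constant of 10 gave 38 and a fit of only the groups compared 28 for KO in PIR-. Residuals of libraries with the same replicate number had a mean r of -0.0096 over 18 pairs, most of them across genotypes. Between the subsets, r was 0.046, -0.046 and 0.030 in wild type and 0.162, 0.041 and 0.062 in KO. Whether the replicate number pairs the samples is therefore open, and the labels do not say. As an added term the replicate number gave 62, 209 and 284 for the KO effects and, within genotype, 44 for the interaction.

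The 6 libraries whose markers field matches the title, where some groups keep 1 library assumed to vary like the others and all PIR+ libraries have the earlier and all PIR- the later source-name day, gave 1053 in wild type, 105 for KO in PIR-, 542 for the KO average and 10 for the interaction. Without the globin-rich libraries, which leaves 7, the counts were 700, 576, 1441, 27, 35 and, for the interaction, 6. These 7 are the 6 libraries above and PIR+ KO replicate 2. The subsets in wild type and KO in PIR- therefore compare the same libraries in both settings, and their counts differ only through the estimated spread. Leaving out single libraries gave 1320 to 2083, 662 to 1418, 2255 to 2849, 28 to 46, 33 to 88, 51 to 138 and 15 to 33, in the order above. PIR+ KO replicate 3 gave the lowest count for the subsets in KO and for both averages, and PIR+ wild-type replicate 3 for the subsets in wild type. The correlation of subset effects was 0.658 with no filter, 0.916 with the filter of 50, 0.746 in the 6 libraries and 0.770 without the globin-rich ones, against 0.837, and 0.813 to 0.839 without single libraries. That of KO effects was 0.0738 to 0.170 without single libraries. camera with an estimated correlation called 3, 2, 2, 0, 3, 1 and 0 lists in the order above, against 9, 6, 8, 5, 6, 5 and 5. fry, which asks another question, called 2 for KO in PIR+, 3 in PIR-, 1 in the KO average and 0 for the interaction, and the test without the globin-rich libraries called 3 in PIR-. Except where stated, the cause was not tested.

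Of the 24 reversed signs 6 belong to called results, those of Plk1 (-0.84 in wild type in the main test) and Hspa5 (0.50 in wild type and 0.33 in the subset average). After median-of-ratios scaling Hspa5 was -0.012 in wild type and -0.12 in the subset average, Il7r -0.052 for KO in PIR-, and Kit -0.0051 for KO in PIR-, -0.0015 in the KO average and 0.0071 in the interaction. With library totals Kit was -0.0076 for KO in PIR+, Il7r -0.039 for KO in PIR- and Hspa5 -0.056 in the subset average. With voom they were -0.018, -0.042 and -0.038. In the 6 libraries Plk1 was 0.018 in wild type, Il7r 0.071 for KO in PIR+ and 0.15 in the KO average, and Kit 0.075 in the interaction. Without the globin-rich libraries Plk1 was 0.018 in wild type and Il7r 0.0502 in the KO average. Without single libraries Kit was -0.051 to 0.26 for KO in PIR+, -0.048 to 0.36 for KO in PIR- and -0.26 to 0.15 in the interaction. Scaling to spike-in totals and DESeq2 were not run. With 3 libraries a group and 208518 to 442714 estimated molecules per library, 14.2% of simulated 1.5-fold changes were found, so small changes were mostly not detectable.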

Other observations

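The tests of Cbfb, of the globin sources, of leaving out the globin-rich libraries, of spike-in scaling and of capture in this part were chosen only after the result was seen, and that of the most abundant genes was set beforehand. Several genes not described above rose in PIR- KO cells. Socs2, a suppressor of cytokine signalling, was 19.7 ± 3.12 in wild type and 57.2 ± 11.6 in KO (mean ± SD, n = 3; log2 fold change 1.48 ± 0.33 SE, adjusted p = 0.00273), and missed the threshold without PIR- KO replicate 3 (1.33, adjusted p = 0.0966, the highest of a range from 5.49e-08) or the globin-rich libraries (1.66, 0.0846). Il12a, which encodes a cytokine subunit, was 8.70 ± 1.81 and 25.6 ± 0.819 (1.47 ± 0.23, adjusted p = 3.81e-06). Il12a was not called without the globin-rich libraries, which leaves 1 wild-type and 2 KO libraries (1.22, adjusted p = 0.0846, the highest of a range from 1.19e-06). Erdr1 was higher in KO in both subsets, 63.9 ± 11.3 and 133 ± 12.4 in PIR- and 158 ± 35.2 and 283 ± 66.6 in PIR+ cells. Notch1, a receptor of T-cell commitment, was 13.7 ± 2.38 and 27.6 ± 7.50 in PIR- cells and 58.1 ± 11.5 and 59.6 ± 15.2 in PIR+ cells. It was called in PIR- cells (0.93) and not without PIR- wild-type replicate 2 (0.83, adjusted p = 0.0892), PIR- KO replicate 3 (0.76, 0.207) or the globin-rich libraries (0.92, 0.241), in a range from 0.00056.

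Sex-linked messages differed between groups. Xist, expressed from the inactive X chromosome, was 31.3 to 34.2 in the 3 PIR+ KO libraries and 2.7 to 18.6 in the other 9. Ddx3y, a gene of the Y chromosome, was 0.8 to 2.0 in PIR+ KO and 4.2 to 9.2 in the other 9 libraries. Both were above 0 in all 12. These genes were chosen after their values were seen. A difference in sex cannot be parted from the groups in KO against wild type in PIR+, in the subsets of KO or in the interaction. The averages over subset and over genotype also include the PIR+ KO libraries, so sex may contribute to them, which was not tested.

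A hypothesis is that Cbfb, which was lower in KO libraries of both subsets, is the gene altered in the KO mice, which the labels do not name. In all 6 KO libraries Cbfb was below every wild-type library of its subset, and so were 5 other tested genes, 6 in all where chance gives 11.4. Cbfb had the largest fall of the 6. The message was still present, 14.6 ± 2.17 in PIR+ and 13.1 ± 6.11 in PIR- KO cells. The hypothesis stays open, since a gene that falls as a consequence may look the same.

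The globin messages of the 5 libraries were set against a single source of RNA. Such a source would give all 5 a like ratio of Hbb-y, an embryonic globin, to Hba-a1. The highest ratio was 273 times the second highest, because PIR+ KO replicate 1 held 773 of Hbb-y and 98.8 of Hba-x, and the other 4 at most 2.7 of Hbb-y. Of the 5 libraries 2 carry the later source-name day and the rest the earlier one. That day follows the markers field in all 12 libraries, and these 5 are all among the 6 whose markers field contradicts the title. The day is therefore no separate record of stage, and it cannot decide whether stage plays a part. Different numbers of red cells or their RNA in single tubes stay open, and a lineage-negative sort is meant to remove such cells.

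The higher sums of PIR+ libraries were set against 3 technical sources. The estimated molecules before scaling had a ratio of 1.33 (exact permutation p = 0.00649, n = 6 each), so scaling by the authors did not create the difference. The value of 1 molecule had a ratio of 0.975 (exact permutation p = 0.803). This value is the factor between those molecules and the sums, so it is no separate test. It argues against deeper libraries or better capture in PIR+ tubes only if the authors' scaling follows the spike-ins. No spike-in rows were available to check that, so depth and capture stay open. Without the 100 most abundant genes the ratio was 1.32 (exact permutation p = 0.00649), which argues against a few abundant genes. More RNA per cell in PIR+ cells and more cells per tube stay open, and neither was tested.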
